A study of Mus musculus with 6 samples.

How the data were processed

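The samples were 6 preparations of RNA from mouse embryonic cardiomyocytes at E12.5, 3 from Yap heterozygous and 3 from Yap knockout embryos. Per the labels' protocols, individual hearts were dissociated with enzymes, green fluorescent cells were sorted, RNA was purified on columns, and biotin-labelled cRNA was made from 0.1 µg of total RNA for hybridisation to an Affymetrix mouse gene array. The groups were taken from the source names of the samples, and the design text of the series describes the replicates as biological. Which embryos shared a litter is not given in the sources used here, nor is whether RNA of several hearts was combined on 1 array.

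The deposited values are probe set intensities on a linear scale, from 2e-05 to 15701, for 35556 probe sets. Per the submitters' processing notes the tool was RMA, a method of background correction, quantile normalization and summarisation, with no version named. RMA gives log2 values, and the intensities deposited by the authors were not on that scale, so the scale was changed back or another summary was used, and which of these applies is not given in the sources used here. The log2 of the intensity was therefore taken here before any test. The design fixed before the data were examined had assumed log2 values and allowed for this step. Values under 1 occurred on at least 1 array for 587 probe sets and for 0 of the tested genes. No detection call was used, so a value near the filter level cannot be told from background, and the fold of such a gene may be understated.

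Probe sets were named from the platform annotation, in which 21789 probe sets had 1 gene symbol, 1621 had several and 12146 had none. Probe sets with several symbols or none were used only in the alternative that tested every probe set. Symbols were updated through Entrez identifiers in a RefSeq gene table of the mouse assembly GRCm38.p6, which matched 21698 of the 21789 probe sets, and the platform's symbol was kept for the others. That table was also used to find which genes neighbour each other, and no coordinates were taken from it. For each of 19938 genes the probe set with the highest mean over the 6 arrays was used. Genes under the 40th percentile of all probe set means, an intensity of 85.7, were left out, which left 13632 genes, 893 of them with several probe sets. Probe sets of near-identical genes can cross-hybridise, and values of such genes are uncertain.

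Gene differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on log2 intensities, with the 2 groups as the only term, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The prior had 3.87 degrees of freedom, and the median SD within a group was 0.080 on the log2 scale. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 37 lists that had at least 3 tested members. The groups added in the closing section were adjusted apart, over those 6 alone. Camera compares a list with all other genes. Camera with an estimated correlation, camera on ranks and fry were the alternatives, and random numbers were seeded. The first 2 principal components held 52.9% and 21.0% of the variance.

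The lists, the main test, the filter and the rule for named genes were fixed before the data were examined. The rule named Yap1, Wwtr1 and Pik3cb in every case, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and in each list all members past the threshold and up to 4 members with the smallest p. Predicted and clone-named genes, 41 of those past the threshold, were not named. Ccn2, Ankrd1, Tnni3k, the collagen genes and the groups added in the closing section fall outside the rule and were chosen after their values were seen. The lists covered Yap1 and its paralog, YAP-TEAD targets, Hippo, PI3K-AKT, growth factor, Wnt and Notch signalling, proliferation, apoptosis, p53 targets, metabolism, hypoxia, stress responses, cytoskeleton, cardiomyocyte structure, regulators and layers, other cell types and sex-linked transcripts.

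The gene test was tested on simulated data, in which 50 genes each were changed by 0.25, 0.5, 1 and 2 on the log2 scale among 13632 genes with the spread of these arrays. It recovered 22%, 80%, 98% and 96% of them, with 13 false calls among 161. Of 100 random lists of unchanged genes, 1 had a camera p under 0.05. The simulated genes were drawn independently, so this does not show how camera behaves for lists whose genes vary together. On the real arrays the estimated correlation was, for example, 0.66 in the mitosis list and 0.19 in the replication list. The alternatives were no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set, quantile normalization, median centring, cyclic loess, a trended and robust prior, array weights, the replicate number as a block, the level of Xist as a covariate, each array left out in turn, an unmoderated linear model and other thresholds. The log2 of the intensity plus 16 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Scanner files were not used here.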

Results

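Gene expression was measured on 6 Affymetrix mouse gene arrays in cardiomyocytes sorted from mouse hearts at E12.5. The embryos carried a Cre recombinase under the cardiac troponin T promoter, a floxed Yap1 gene and the mTmG reporter, which turns a cell green once Cre has acted. The green cells were collected by flow cytometry. Of the 6 arrays, 3 came from Yap heterozygous embryos (Yap HET) and 3 from Yap knockout embryos (Yap KO), described as biological replicates. The deposited values were intensities on a linear scale, and the median over all probe sets was 136, 132 and 140 on the Yap HET arrays and 133, 130 and 128 on the Yap KO arrays. Correlations of log2 intensity over the tested genes, which are not independent replicates, lay between 0.992 and 0.996 within a group and between 0.984 and 0.991 across groups. In the text that follows, log2 changes are Yap KO minus Yap HET with their standard error (SE), mean intensities carry the SD of 3 arrays, and adjusted p-values for genes come from limma with Benjamini-Hochberg adjustment over 13632 genes. The number of arrays limits the precision of every value.

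The comparison of Yap KO with Yap HET cells addresses the question posed in the title of the series, namely how the Hippo effector Yap and PI3K-AKT signalling are connected through Pik3cb in the proliferation and survival of cardiomyocytes. Yap1, which encodes a transcriptional coactivator restrained by the Hippo kinases, was the gene with the lowest p-value. Its intensity was 895 ± 28.9 (SD) in Yap HET cells and 91.5 ± 10.3 in Yap KO cells. This was a log2 change of -3.29 ± 0.08 (SE) and a 9.81-fold lower level (limma adjusted p = 2.70e-06). The 3 Yap KO arrays read 103, 84.7 and 86.6, close to the level of 85.7 under which probe sets were left out, so the fold may understate the loss. Where the single Yap1 probe set lies relative to the deleted exons is not given in the sources used here. Wwtr1, which encodes the paralog TAZ, had 819 ± 24.9 in Yap HET and 852 ± 31.7 in Yap KO cells, a log2 change of 0.06 ± 0.05 that did not pass the test (limma adjusted p = 0.53). Pik3cb, which encodes the p110-beta catalytic subunit of phosphoinositide 3-kinase, fell from 617 ± 10.1 to 487 ± 10.1, a 1.27-fold lower level (log2 change -0.34 ± 0.05, limma adjusted p = 0.0063). All 3 Yap KO values of Pik3cb lay below all 3 Yap HET values.

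**Figure D1:**
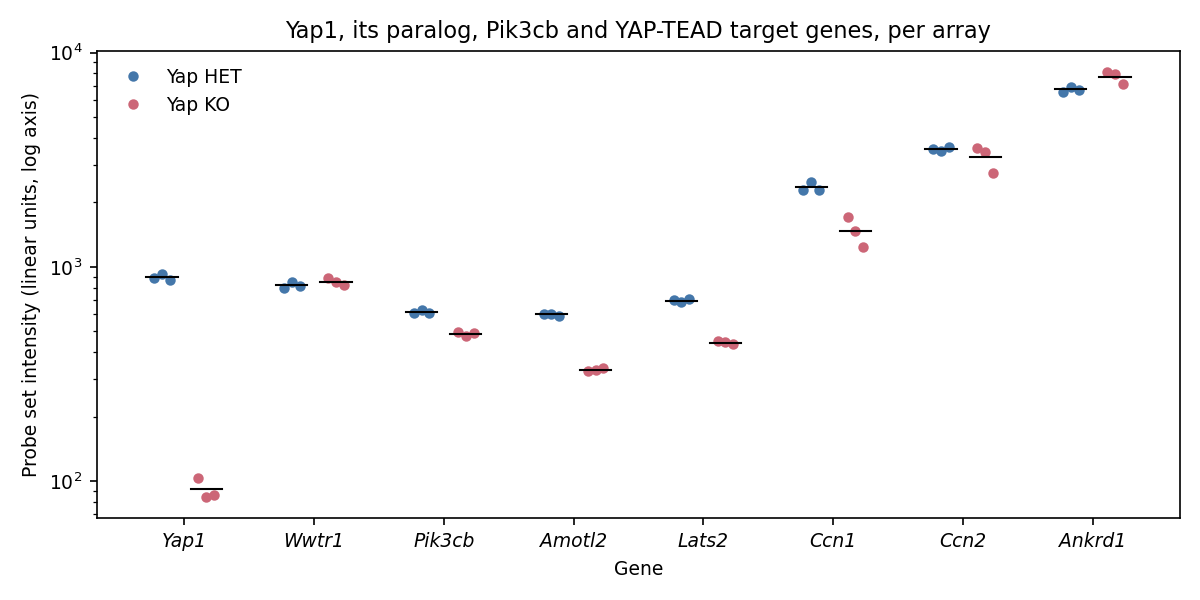
Probe set intensity (linear units on a log axis) of 8 genes on each of the 6 arrays, with Yap HET in blue, Yap KO in red and the group mean as a black line. Yap1 dropped from 895 to 91.5 and Pik3cb from 617 to 487, while the differences of Wwtr1, Ccn2 and Ankrd1 did not pass the test.

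Across the transcriptome, 704 genes were higher and 649 lower in Yap KO cells, 1353 of 13632 genes tested (limma, adjusted p under 0.05). Most changes were small: the median absolute log2 change among these genes was 0.33, and 15 genes were at least 2-fold higher and 6 at least 2-fold lower. The largest rises were in Gal, which encodes the neuropeptide galanin (log2 change 1.74 ± 0.16), Prmt8, an arginine methyltransferase (1.52 ± 0.15), and Rxrg, a retinoid X receptor (1.37 ± 0.16). Next were Slc35d3 (1.34 ± 0.08), Nptx2, a neuronal pentraxin (1.33 ± 0.09), and Has2, the main hyaluronan synthase of the embryonic heart (1.29 ± 0.05). They were followed by Ache, the gene of acetylcholinesterase (1.26 ± 0.13), H2-Ab1, a class II histocompatibility gene (1.19 ± 0.21), the phosphodiesterase gene Pde1a (1.18 ± 0.06), the transcription factor gene Ebf1 (1.14 ± 0.12), Ccdc3 (1.12 ± 0.18) and Pla2g7, a phospholipase (1.11 ± 0.08). After Yap1, the largest falls were in Ogn, which encodes the matrix proteoglycan osteoglycin (-2.08 ± 0.11), Vnn1, a pantetheinase (-1.87 ± 0.09), Plscr2, a phospholipid scramblase (-1.32 ± 0.09), and the tight junction gene Cldn11 (-1.28 ± 0.10). Naaladl2 (-1.07 ± 0.08), the Wnt inhibitor gene Tmem88 (-0.997 ± 0.14), Egfl6 (-0.96 ± 0.17), Tm4sf5 (-0.94 ± 0.15), the transcription factor genes Tfcp2l1 (-0.93 ± 0.06) and Sox3 (-0.89 ± 0.08), and Car2, a carbonic anhydrase (-0.91 ± 0.05), completed the 12 largest falls. Of these genes, Prmt8, Slc35d3 and Pde1a had Yap HET means (61.8, 80.9 and 73.1) and Ogn, Vnn1, Plscr2, Cldn11 and Egfl6 had Yap KO means (50.6, 79.4, 65.9, 63.3 and 66.2) under the filter level of 85.7. Their dim side cannot be told from background, so their changes may be understated and their ranks are uncertain. H2-Ab1 also read under this level on Yap HET replicates 1 and 3 (80.1 and 70.0), and Rxrg on Yap HET replicate 1 (75.2). The limma adjusted p-values of these 24 genes were at most 0.0152, reached by Egfl6. The count of 1353 fell to 434 without Yap HET replicate 1, 433 without Yap KO replicate 2, 689 without Yap HET replicate 3 and 700 without Yap KO replicate 3. Of these called genes 424, 424, 659 and 650 were among the 1353. All 1353 had Yap KO values that did not overlap the Yap HET values, as did 33.9% of all genes tested against 10% by chance.

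**Figure D2:**
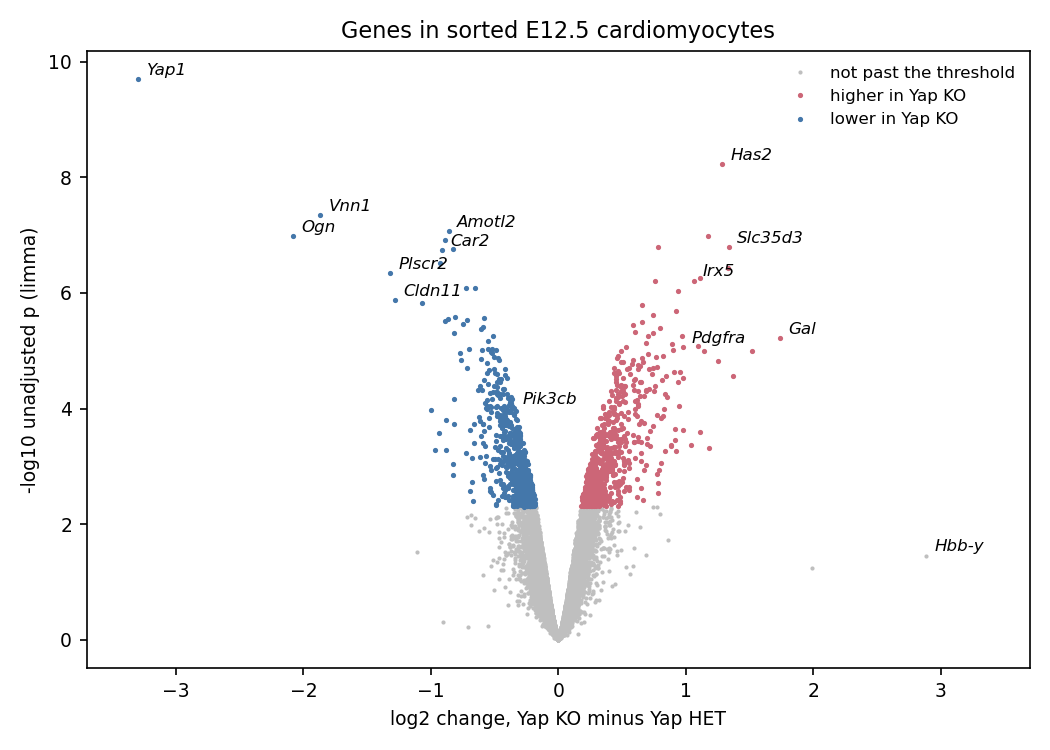
Log2 change (Yap KO minus Yap HET, horizontal) against the -log10 of the unadjusted limma p (vertical) for 13632 genes, with the 704 genes that were higher in red, the 649 that were lower in blue and genes not past the threshold in grey. Yap1 has the lowest p, and the globin gene Hbb-y has a large change without passing the test.

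Genes listed as targets of YAP and TEAD factors moved both ways, with more falls than rises. Whether these factors control them directly in these cells was not tested. Of 25 YAP-TEAD target genes tested, 8 fell and 3 rose over all genes, against 9.93% of all genes tested that changed. Adjusted over the list alone, 11 fell and 6 rose. The falls included Amotl2, an angiomotin family gene (599 ± 6.83 to 331 ± 4.18, log2 change -0.86 ± 0.05), the Hippo kinase gene Lats2 (-0.65 ± 0.05), the matricellular gene Ccn1 (-0.69 ± 0.11) and Ajuba, a LIM domain gene (-0.61 ± 0.10). Nt5e, which encodes an ecto-nucleotidase, rose by 0.59 ± 0.06, and Tgfb1, a growth factor gene, by 0.42 ± 0.07. Ccn2 and Ankrd1, named after their values were seen, had log2 changes of -0.14 ± 0.10 (limma adjusted p = 0.41) and 0.20 ± 0.06 (limma adjusted p = 0.091). The list had a median log2 change of -0.09 and did not pass the set test (camera adjusted p = 0.19). That test looks for a shift in 1 direction and does not measure how many members changed. The 8 falls became 4 without Yap HET replicate 1 and 5 without Yap KO replicate 2 or Yap KO replicate 3.

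Within the Hippo pathway itself, 7 of 27 genes fell and 3 rose, against 9.93% of all genes tested that changed. Adjusted over the list alone, 8 fell and 5 rose. Amotl2, Lats2 and the phosphatase gene Ptpn14 (-0.37 ± 0.05) are in both lists. Tead4, one of the TEAD transcription factor genes (-0.62 ± 0.09), also fell, as did Wwc2, a scaffold gene (-0.33 ± 0.07). The atypical cadherin genes Fat4 (0.63 ± 0.11) and Dchs1 (0.39 ± 0.06) and the kinase activator gene Mob1b (0.37 ± 0.05) rose. The median of the list was 0.01, its mean -0.07 and the direction of the set test down (camera adjusted p = 0.60). The 7 falls became 4 without Yap HET replicate 1, Yap KO replicate 2 or Yap KO replicate 3.

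Genes of the PI3K-AKT pathway changed in both directions. Of 32 tested, 3 fell, Pik3cb among them, and 2 rose, against 9.93% of all genes tested that changed, and 3 fell and 3 rose adjusted over the list alone. The regulatory subunit gene Pik3r3 rose by 0.50 ± 0.06 and the lipid phosphatase gene Inpp4b by 0.51 ± 0.06, and the AKT phosphatase genes Phlpp2 (-0.29 ± 0.06) and Phlpp1 (-0.22 ± 0.06) fell. The median of the list was -0.002, its mean 0.02 and its set test up but not past the threshold (camera adjusted p = 0.62). The 3 falls became 1 without Yap HET replicate 1, Yap KO replicate 2 or Yap KO replicate 3, and Pik3cb kept its call in each case. Among genes of IGF and receptor tyrosine kinase signalling, 4 of 25 rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone. The receptor genes Pdgfra (0.98 ± 0.10), Pdgfrb (0.73 ± 0.08) and Kit (0.52 ± 0.10) and the binding protein gene Igfbp7 (0.44 ± 0.11) rose, whereas Igfbp2 (-0.48 ± 0.06) and the neuregulin coreceptor gene Erbb2 (-0.20 ± 0.05) fell. The median was 0.11 (camera adjusted p = 0.029), and adjusted p = 0.77 with an estimated correlation. The call also ended with a stricter filter on dim probe sets (camera adjusted p = 0.195) and with cyclic loess (camera adjusted p = 0.080). The 2 falls became 1 whichever array was left out, and the 4 rises became 2 without Yap KO replicate 3. Pdgfra and Pdgfrb are also markers of mesenchymal cells and pericytes, a group described with the other cell types.

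Genes that start and carry out DNA replication fell as a group. Of 39 genes of the G1/S transition and DNA replication, 24 fell and 0 rose over all genes. Adjusted over the list alone, 32 fell and 0 rose, and 1 was higher at an unadjusted limma p under 0.05. The replication licensing genes Cdt1 (1084 ± 56.6 to 740 ± 5.31, log2 change -0.55 ± 0.05) and Cdc6 (-0.56 ± 0.06) and the helicase genes Mcm5 (-0.42 ± 0.05) and Mcm7 (-0.38 ± 0.05) were among them. So were the initiation factor gene Mcm10 (-0.48 ± 0.05), the DNA polymerase epsilon gene Pole (-0.46 ± 0.09) and the transcription factor gene E2f1 (-0.32 ± 0.06). The median log2 change was -0.26 (camera adjusted p = 1.31e-14). With an estimated correlation the camera adjusted p was 0.77 and the unadjusted p 0.029. Genes of mitosis and cytokinesis had a median of -0.12 over 35 members (camera adjusted p = 9.63e-05), and adjusted p = 0.84 with an estimated correlation. Of these, 3 fell and 0 rose, 2 fell and 0 rose adjusted over the list alone, and 12 were lower and 0 higher at an unadjusted limma p under 0.05. The cytokinesis gene Ect2 (-0.28 ± 0.06) and the mitotic kinase genes Aurkb (-0.22 ± 0.05) and Plk1 (-0.22 ± 0.06) fell. The mean of the replication list fell by 0.133 more than that of the mitosis list (two-sided exact permutation p = 0.1 over the arrays, the smallest that 3 arrays against 3 allow). Among 18 cell-cycle inhibitors, Ccng2 (0.50 ± 0.07), the CDK inhibitor gene Cdkn2d (0.35 ± 0.07) and the retinoblastoma gene Rb1 (0.22 ± 0.05) rose and Gas1 (-0.31 ± 0.06) fell, 3 and 3 adjusted over the list alone. This list had a median of 0.02 (camera adjusted p = 0.62). The 24 replication genes that fell became 7 without Yap HET replicate 1 and 9 without Yap KO replicate 2 or Yap KO replicate 3. The 3 mitosis genes became 1 without Yap HET replicate 2 or Yap KO replicate 1 and 0 without any other array. Among the cell-cycle inhibitors, the 3 rises became 1 without Yap HET replicate 1, Yap KO replicate 2 or Yap KO replicate 3, and the 1 fall became 2 without Yap HET replicate 2 and 0 without any other array except Yap KO replicate 3. The set tests of the replication and mitosis lists stayed past the threshold without any single array, with medians between -0.28 and -0.23 for replication and between -0.16 and -0.08 for mitosis, the latter without Yap KO replicate 2.

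**Figure D3:**
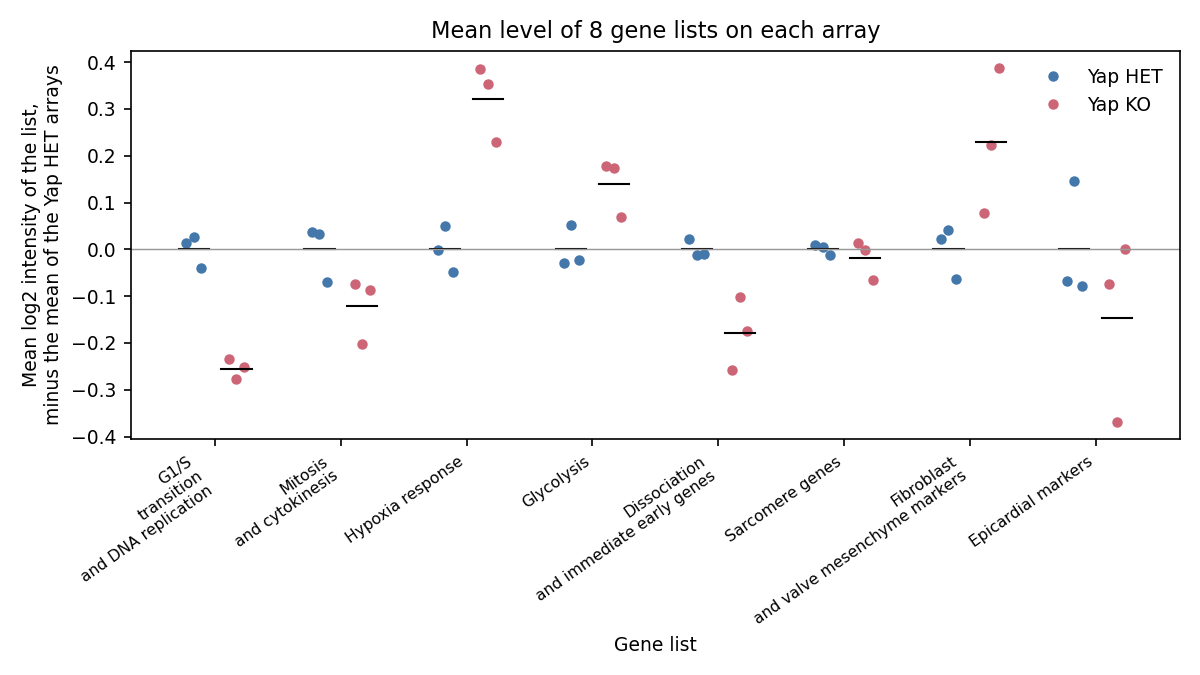
Mean log2 intensity of 8 gene lists on each array, minus the mean of the 3 Yap HET arrays, with Yap HET in blue, Yap KO in red and the group mean as a black line. The 3 Yap KO arrays lie below all Yap HET arrays for the replication genes and above them for the hypoxia genes.

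Genes of cell death and survival moved both ways, with 3 rises and 2 falls over the pro-apoptotic and anti-apoptotic lists. Of 22 pro-apoptotic genes, Bnip3, a mitochondrial gene induced by low oxygen (0.59 ± 0.07), rose, and the mitochondrial protease gene Htra2 (-0.38 ± 0.05) and the BH3-only gene Bid (-0.36 ± 0.05) fell, with the same 1 and 2 genes adjusted over the list alone. The median log2 change was -0.03 (camera adjusted p = 0.92). Of 13 anti-apoptotic genes, 2 rose and 0 fell, and 4 rose and 0 fell adjusted over the list alone, with 0 lower at an unadjusted limma p under 0.05. Birc3, an inhibitor of apoptosis that lies next to Yap1 in the annotation together with Birc2, rose by 0.48 ± 0.06 and Api5 by 0.23 ± 0.05, and Birc2 had a log2 change of 0.30 ± 0.08 (limma adjusted p = 0.062). The median of the list was 0.08 (camera adjusted p = 0.053). The 2 rises became 1 without any array except Yap HET replicate 2. Of 20 p53 target genes, 0 passed the threshold with limma, over all genes or adjusted over the list alone, while 3 were higher and 3 lower at an unadjusted p under 0.05. The median was 0.03 (camera adjusted p = 0.57). Without Yap KO replicate 1, 1 p53 target gene fell.

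Genes induced by low oxygen were higher in Yap KO cells. Of 21 hypoxia response genes, 12 rose and 0 fell. Adjusted over the list alone, 16 rose and 0 fell, with 0 lower at an unadjusted limma p under 0.05. The oxygen sensor genes Egln3 (412 ± 37.3 to 763 ± 61.8, log2 change 0.89 ± 0.09) and Egln1 (0.35 ± 0.06), the mTOR inhibitor gene Ddit4 (0.51 ± 0.10), Ndrg1 (0.48 ± 0.08), the mitochondrial gene Higd1a (0.46 ± 0.07) and the collagen hydroxylase gene P4ha1 (0.41 ± 0.08) rose. The median was 0.35 (camera adjusted p = 2.81e-09), and adjusted p = 0.77 with an estimated correlation. Of 23 glycolysis genes, 4 of which are also in the hypoxia list, 4 rose and 0 fell, and 5 rose and 1 fell adjusted over the list alone. The 4 that rose over all genes were the glucose transporter gene Slc2a3 (0.67 ± 0.14), the hexokinase gene Hk2 (0.48 ± 0.10), the pyruvate dehydrogenase kinase gene Pdk1 (0.35 ± 0.07) and the lactate transporter gene Slc16a3 (0.31 ± 0.06). The median was 0.08 (camera adjusted p = 8.34e-04), and adjusted p = 0.82 with an estimated correlation. Of 28 fatty acid oxidation genes, Acot2 (-0.30 ± 0.06) was the 1 gene that changed, also adjusted over the list alone. The list median stood at -0.003 (camera adjusted p = 0.82). Of 42 respiratory chain genes the 1 change, again also adjusted over the list alone, was in Ndufa1 (0.38 ± 0.07). The median was -0.005, the mean 0.01 and the set test up (camera adjusted p = 0.71). The 12 hypoxia genes became 4 without Yap KO replicate 2, 5 without Yap HET replicate 1, 6 without Yap KO replicate 1 and 7 without Yap HET replicate 3, and 1 fell without Yap KO replicate 3. The fatty acid oxidation list went from 1 fall to 0 without Yap HET replicate 1 or Yap KO replicate 2 and to 2 without Yap KO replicate 1, and had 2 rises without Yap HET replicate 2. The respiratory chain list went from 1 rise to 2 without Yap HET replicate 2 and to 0 without any other array except Yap KO replicate 1. The 4 glycolysis genes became 0 without Yap HET replicate 1 or 3 or without Yap KO replicate 1 or 2, while the set tests of the hypoxia and glycolysis lists stayed past the threshold without any single array.

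Immediate early genes, which respond within minutes to tissue dissociation, moved with the same comparison in the opposite direction to the hypoxia genes. Of 30 dissociation and immediate early genes, 7 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone. Nr4a1 (-0.56 ± 0.06), Atf3 (-0.44 ± 0.07), Egr2 (-0.41 ± 0.06) and Fos (-0.39 ± 0.06) fell, as did the heat shock gene Hspa1a (-0.82 ± 0.16). Hspa1a has a near-identical copy, Hspa1b, so its value is uncertain. Myc rose by 0.30 ± 0.05. The median was -0.18 (camera adjusted p = 2.21e-04), and adjusted p = 0.77 with an estimated correlation. The 7 falls became 4 without Yap HET replicate 1. Of 30 genes of the integrated and endoplasmic reticulum stress responses, the serine synthesis genes Phgdh (-0.51 ± 0.10) and Psat1 (-0.41 ± 0.06) and the amino acid transporter gene Slc7a5 (-0.26 ± 0.05) fell and Vldlr (0.34 ± 0.07) rose, with the same counts adjusted over the list alone. This list had a median of -0.02 (camera adjusted p = 0.60). Of 23 antioxidant genes, Gclc, needed for glutathione synthesis (-0.35 ± 0.08), and Txnrd2 (-0.22 ± 0.05) fell, also adjusted over the list alone. The list median stood at -0.03 (camera adjusted p = 0.71). In the integrated and endoplasmic reticulum stress list, the 3 falls became 1 without Yap KO replicate 2 or 3, and the 1 rise became 0 without any array except Yap KO replicate 3. The 2 antioxidant falls became 1 without Yap HET replicate 3 and 0 without any other array, and 1 antioxidant gene rose without Yap HET replicate 2.

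Markers of trabecular myocardium, the inner layer of the ventricular wall, were higher in Yap KO cells, and 3 markers of the compact outer layer were lower. Of 12 trabecular markers, 4 rose and 0 fell, and 6 rose and 0 fell adjusted over the list alone, with 0 lower at an unadjusted limma p under 0.05. The rises were in the transcription factor genes Irx3 (0.63 ± 0.10) and Etv1 (0.47 ± 0.05) and the natriuretic peptide genes Nppb (0.39 ± 0.08) and Nppa (0.19 ± 0.05). The median was 0.15 (camera adjusted p = 0.0028), and adjusted p = 0.77 with an estimated correlation. Of 8 compact layer markers, 3 fell and 0 rose, and 4 fell and 0 rose adjusted over the list alone, with 1 higher at an unadjusted limma p under 0.05. The slow skeletal troponin gene Tnnt1 (-0.61 ± 0.06), the Notch effector gene Hey2 (-0.53 ± 0.10) and the proliferation regulator gene Mycn (-0.48 ± 0.06) fell. The median log2 change was -0.20 (camera adjusted p = 0.11). The 4 trabecular genes that rose became 2 without Yap HET replicate 1 or 3 or without Yap KO replicate 1 or 2. Of the trabecular markers, 4 (Bmp10, Gja5, Nppa and Sln) are also in the atrial list. Nppa and Nppb are also in the natriuretic peptide and stress list, so the trabecular list is not particular to that layer. Of 16 atrial markers, 3 rose, among them Dkk3 (0.29 ± 0.06), and 1 fell, the transcription factor gene Nr2f1 (-0.29 ± 0.07), against 6 and 2 adjusted over the list alone. The median log2 change was 0.06 (camera adjusted p = 0.19). Of 12 ventricular markers, Kcne1 (0.49 ± 0.06) and Mpped2 (0.38 ± 0.08) rose and Hey2 fell, 2 and 2 adjusted over the list alone. The median was -0.001, the mean 0.01 and the set test up (camera adjusted p = 0.62). The 3 atrial rises became 0 without Yap HET replicate 1 or 3 or Yap KO replicate 1 or 2 and 1 without Yap KO replicate 3, and the atrial fall was lost whichever array was left out. The 2 ventricular rises became 1 without Yap HET replicate 1 or 3 or Yap KO replicate 1 or 2, and the ventricular fall was lost without Yap HET replicate 1 or 3.

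Genes of the contractile apparatus, heart development and excitation moved both ways. Of 37 sarcomere genes, the titin-binding gene Tcap (0.33 ± 0.07) and the M-band gene Myom2 (0.56 ± 0.11) rose and Tnnt1 and the myosin gene Myh7b (-0.66 ± 0.17) fell, with the same counts adjusted over the list alone. The median was 0.01, the mean -0.02 and the set test up (camera adjusted p = 0.92). Of 30 cardiac transcription factors, 4 rose and 4 fell, and 6 rose and 5 fell adjusted over the list alone. Irx5 (1.07 ± 0.07), Irx3 and the T-box genes Tbx3 (0.47 ± 0.09) and Tbx2 (0.34 ± 0.08) rose, and Hey2, Mycn, Prox1 (-0.24 ± 0.05) and Nr2f1 fell. The median was -0.04, the mean 0.005 and the set test down (camera adjusted p = 0.65). Of 30 genes of calcium handling and ion channels, 5 rose and 3 fell, and 10 rose and 4 fell adjusted over the list alone. The potassium channel subunit gene Kcne1 and the calsequestrin gene Casq1 (0.36 ± 0.06) rose, whereas Kcnq1, the channel gene whose product Kcne1 modulates (-0.52 ± 0.05), and Casq2, the cardiac calsequestrin gene (-0.49 ± 0.09), fell. The median of the list was 0.10 (camera adjusted p = 0.053). Of 17 natriuretic peptide and stress genes, Nppb and Nppa rose and the small heat shock gene Hspb1 (-0.29 ± 0.07) fell, 3 and 4 adjusted over the list alone. The median was -0.06 (camera adjusted p = 0.55). The 2 sarcomere rises became 0 without Yap HET replicate 3 or Yap KO replicate 2 and 1 without Yap HET replicate 1 or Yap KO replicate 1 or 3, and the 2 sarcomere falls became 1 without any array except Yap KO replicate 1. Among the transcription factors, the 4 rises became 2 without Yap HET replicate 1, and the 4 falls became 1 without Yap HET replicate 1 or 3 and 2 without Yap KO replicate 2 or 3. In the calcium and channel list, the 5 rises became 1 without Yap HET replicate 1 and 2 without Yap HET replicate 3 or Yap KO replicate 1 or 2, and the 3 falls became 1 without Yap KO replicate 3. In the natriuretic peptide and stress list, the 2 rises became 1 without Yap HET replicate 2 or Yap KO replicate 3 and 0 without any other array, and the 1 fall became 2 without Yap KO replicate 1 and 0 without any other array.

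Genes of the Notch pathway moved both ways, and the Wnt target and adhesion genes that changed were higher. Of all genes tested, 9.93% passed the threshold. Of 18 Notch pathway genes, 3 rose and 2 fell, and 4 rose and 2 fell adjusted over the list alone. The receptor gene Notch1 (0.41 ± 0.07) and the target gene Heyl (0.40 ± 0.06) rose and Notch2 (-0.38 ± 0.06) fell. This list had a median of 0.04 (camera adjusted p = 0.31). Of 14 Wnt-beta-catenin target genes, Myc and the mesenchymal transcription factor gene Snai2 (0.52 ± 0.12) rose, also adjusted over the list alone. The list median stood at 0.03 (camera adjusted p = 0.46). Of 36 actin cytoskeleton and adhesion genes, the integrin genes Itgav (0.53 ± 0.05) and Itga6 (0.42 ± 0.07) and the actin-binding gene Tagln2 (0.36 ± 0.06) rose and 0 fell, also adjusted over the list alone, with 6 lower at an unadjusted limma p under 0.05. The median was 0.05 (camera adjusted p = 0.14). The 3 Notch rises became 1 without Yap HET replicate 1 or Yap KO replicate 2, and the 2 Notch falls became 1 without Yap HET replicate 1 or 3. The 2 Wnt target rises became 1 without Yap HET replicate 1 or 3 or Yap KO replicate 2 or 3, and 2 adhesion genes fell without Yap KO replicate 1.

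Markers of other cell types of the heart were measured in the same sorted cells, and those of fibroblasts and valve mesenchyme were higher in Yap KO cells. Of 20 markers of fibroblasts and valve mesenchyme, 7 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone. Pdgfra (358 ± 40.9 to 706 ± 62.5), the matrix genes Tnc (0.82 ± 0.12), Postn (0.72 ± 0.13), Col6a1 (0.45 ± 0.05) and Vcan (0.33 ± 0.05) and the transcription factor genes Tcf21 (0.93 ± 0.17) and Sox9 (0.39 ± 0.07) rose, and Ogn fell. The median was 0.32 (camera adjusted p = 9.63e-05), and adjusted p = 0.77 with an estimated correlation. The 7 rises became 12 without Yap KO replicate 1, and without Yap KO replicate 3 the 1 fall became 2 and the median 0.17, with the set test past the threshold without any single array. Of 19 endothelial and endocardial markers, the receptor genes Kdr (0.76 ± 0.05) and Eng (0.52 ± 0.08), Ramp2 (0.35 ± 0.09) and Nfatc1, an endocardial transcription factor gene (0.31 ± 0.08), rose and Ecscr (-0.46 ± 0.05) and Npr3 (-0.34 ± 0.06) fell, 7 and 2 adjusted over the list alone. The median log2 change was 0.09 (camera adjusted p = 0.19). Of 16 epicardial markers, Tcf21, shared with the fibroblast list, rose and Rspo1 (-0.39 ± 0.08) fell, 1 and 3 adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.19). Of 12 smooth muscle and pericyte markers, Pdgfrb and Cspg4 (0.34 ± 0.07) rose, 3 up and 1 down adjusted over the list alone. The median was -0.07, the mean 0.03 and the set test up (camera adjusted p = 0.71). Of 11 macrophage and leukocyte markers, the lysozyme genes Lyz1 (0.81 ± 0.16) and Lyz2 (0.47 ± 0.11) rose, 2 up and 5 down adjusted over the list alone. This list had a median of -0.12 (camera adjusted p = 0.43). The lysozyme genes are near-identical copies, so their separate values are uncertain. With 1 array left out, the 4 endothelial rises became 2 without Yap HET replicate 2 or Yap KO replicate 2, and the 2 falls became 1 without Yap HET replicate 1. The 1 epicardial rise became 0 without Yap HET replicate 1 or Yap KO replicate 3 and 2 without Yap KO replicate 2, and the 1 epicardial fall became 0 without Yap HET replicate 1 or Yap KO replicate 2 and 2 without Yap KO replicate 3. The 2 pericyte rises became 1 without Yap HET replicate 1 or 3 or Yap KO replicate 2, and 1 gene fell without Yap KO replicate 1. The 2 leukocyte rises became 0 without Yap HET replicate 1 or 3 or Yap KO replicate 2 and 1 without Yap KO replicate 1 or 3, and 1 leukocyte marker fell without Yap HET replicate 2 or Yap KO replicate 1.

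**Figure D4:**
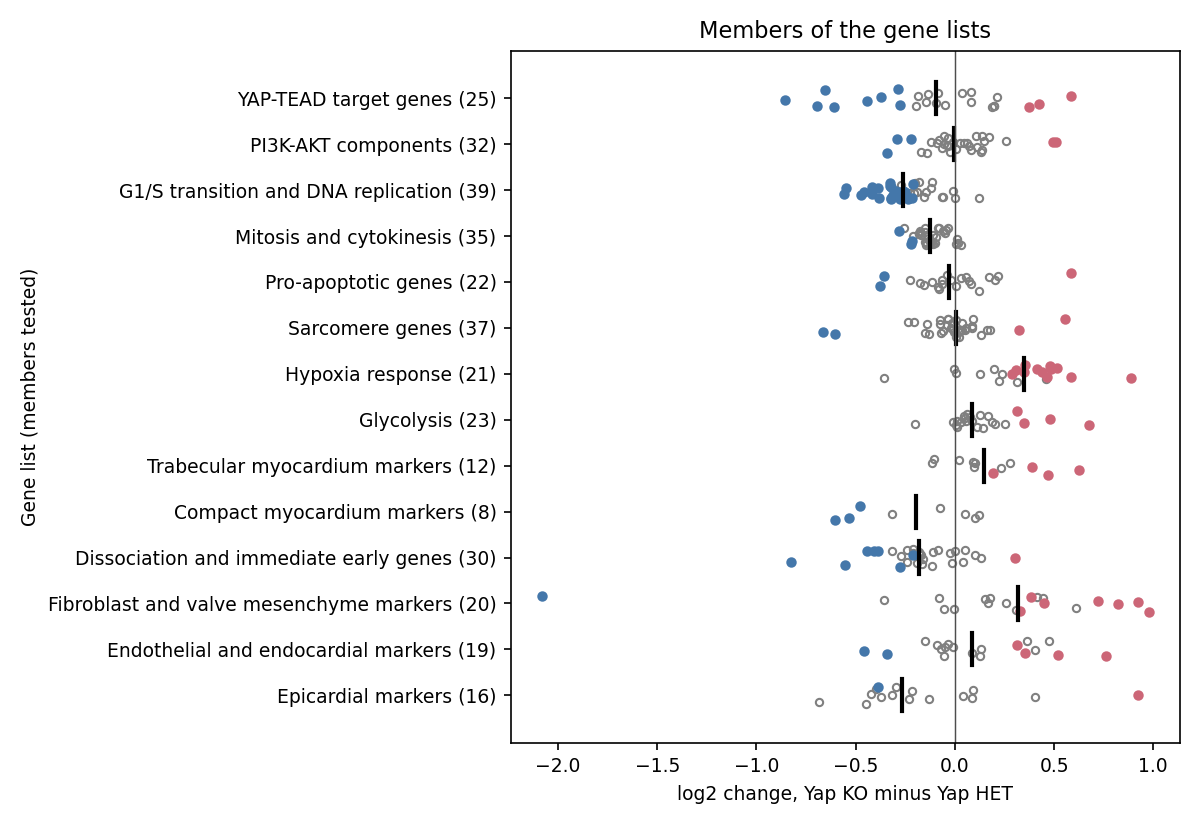
Log2 change (Yap KO minus Yap HET) of each tested member of 14 gene lists, with members that rose in red, members that fell in blue, others as open grey circles and the median of each list as a black bar. The medians run from -0.26 for the replication and epicardial lists to 0.35 for the hypoxia list.

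Of 10 erythroid markers, Car2 fell and 0 rose over all genes, 1 up and 1 down adjusted over the list alone, with 2 higher at an unadjusted limma p under 0.05. This list had a median of 0.09 (camera adjusted p = 0.62). The embryonic globin gene Hbb-y read 232, 27.1 and 19.8 on the Yap HET arrays and 1295, 450 and 86.3 on the Yap KO arrays, a log2 change of 2.89 ± 1.14 that did not pass the test (limma adjusted p = 0.145). Globin genes have near-identical copies, and the Yap HET values of 27.1 and 19.8 lay under the filter level and cannot be told from background, so this value is uncertain. The alpha-type globin gene Hba-x read 166, 41.1 and 32.1 on the Yap HET arrays and 822, 227 and 73.4 on the Yap KO arrays. This was the same order of arrays, but 41.1, 32.1 and 73.4 also lay under the filter level. The globin gene Hbb-bh1 had another order, with 178, 122 and 156 on the Yap HET arrays and 349, 205 and 154 on the Yap KO arrays. Whether the share of erythroid RNA differed between arrays was not tested. Of 7 neural crest and neuronal markers, 0 passed the threshold over all genes with limma, 1 rose and 1 fell adjusted over the list alone, and 1 was higher and 2 lower at an unadjusted p under 0.05. The list median stood at -0.03 (camera adjusted p = 0.62). Of 12 skeletal muscle markers, the fast troponin gene Tnni2 (-0.29 ± 0.06) fell, also adjusted over the list alone. The list median stood at -0.06 (camera adjusted p = 0.62). Of 4 sex-linked transcripts, 0 passed the threshold with limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (median -0.63, camera adjusted p = 0.82). Xist, expressed from the inactive X chromosome of females, read 2112, 2313 and 600 on the Yap HET arrays and 3015, 988 and 1356 on the Yap KO arrays. The Y-linked gene Uty read 136, 107 and 430 on the Yap HET arrays and 11.0, 391 and 332 on the Yap KO arrays. The Y-linked gene Eif2s3y read 305, 191 and 788 on the Yap HET arrays and 19.7, 691 and 515 on the Yap KO arrays. On the arrays other than Yap KO replicate 1, Xist and both Y-linked genes lay above the filter level of 85.7. Female and male transcripts on the same array argue against RNA of 1 heart on those arrays. The Xist reading of male cells alone was not measured, and whether hearts were combined is not given in the sources used here. With 1 array left out, 1 erythroid marker rose without Yap KO replicate 3 and 2 fell without Yap HET replicate 2, 1 neural marker rose without Yap HET replicate 2, and the skeletal muscle fall was lost without Yap HET replicate 1 or 3 or Yap KO replicate 1 or 2. Over all 37 lists, 8 passed the camera test with its preset correlation and 0 did with an estimated correlation, where 1 had an unadjusted p under 0.05. With fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, 7 lists passed.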

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

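The log2 with an offset of 16 was chosen after seeing the data, and the other alternatives were fixed before. Yap1 (log2 change -3.39 to -3.09, adjusted p 2.29e-13 to 0.0127) and Pik3cb (-0.36 to -0.33, adjusted p 5.79e-04 to 0.0364) kept direction and call under all 18 alternatives that test genes. No gene list and no named gene past the threshold reversed. With an array left out this was fixed in advance for those genes, since their groups did not overlap. Of 739 list results, 704 kept their side of the threshold, 14 lost a call and 21 gained one. The scalings (quantile, median centring, cyclic loess) left the share of calls that were higher between 50.9% and 56.7%, against 52.0%. Of 167 named genes past the threshold, 79 lost the call with no filter, 124 with the unmoderated model, 56 with the replicate block and between 30 and 85 with an array left out.

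The count past the threshold, with the higher and lower genes in brackets, was 508 (271 and 237) with no filter, 872 (445 and 427) with every probe set, 2246 (1189 and 1057) with a trended and robust prior, 4617 (2038 and 2579) with array weights, which gave Yap HET replicate 1 a weight of 7.60, and 231 (94 and 137) with the unmoderated model. It was 2411 (1216 and 1195) at an adjusted p under 0.10, 311 (161 and 150) under 0.01, 21 (15 and 6) with at least a 2-fold change and 3851 (1889 and 1962) at an unadjusted p under 0.05, which follow from the thresholds. The cause of the other differences was not tested. Whether a replicate number marks a shared litter or day is not given in the sources used here. For this reason the design fixed before the data were examined left the arrays unpaired. Deviations of same-numbered arrays from their group means were correlated at -0.08, -0.17 and 0.12. With 3 arrays per group these values cannot settle whether the arrays were pairs. Of the 6 arrays, 1 had their best correlation with the other group at their own number. With the replicate block the count was 698 (395 and 303). With an array left out it ranged from 433 to 1375 (higher 214 to 783, lower 206 to 597), with higher genes falling to 441 without Yap KO replicate 1. Of the 1353 genes 100% kept their direction, which was fixed in advance. Their groups did not overlap, so leaving out an array could not turn the sign.

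With an estimated correlation 0 lists passed, and the calls were lost by the IGF and receptor list (median 0.11), mitosis (-0.12), replication (-0.26), glycolysis (0.085), hypoxia (0.35), dissociation (-0.18), trabecular (0.15) and fibroblast lists (0.32). Under fry the mitosis (-0.12), glycolysis (0.085), dissociation (-0.18) and fibroblast (0.32) lists lost the call and the YAP-TEAD (-0.094), Notch (0.039) and compact layer (-0.20) lists gained it, and the cause was not tested. The IGF and receptor list lost the call with the stricter filter (0.11) and cyclic loess (0.14). Calls were gained by the YAP-TEAD list with the stricter filter (-0.15), the compact layer list with the trended prior (-0.20) and the atrial list with array weights (0.086). The anti-apoptotic list gained one with no filter (0.078), median centring (0.076), the replicate block (0.081) and the Xist covariate (0.073). The calcium and channel list did with no filter (0.10), the mean of probe sets (0.10), the trended prior (0.10), array weights (0.10) and the Xist covariate (0.10). With an array left out, the medians ranged from 0.051 to 0.099 for the anti-apoptotic list, which passed without Yap HET replicate 1 or 2 or Yap KO replicate 2, from 0.089 to 0.12 for the calcium list, which passed without Yap HET replicate 3 or Yap KO replicate 3, and from -0.30 to -0.20 for the epicardial list, which passed without Yap KO replicate 3. Signal near background limits the folds of Yap1 in Yap KO cells and of the 8 genes named among the largest changes with a group mean under the filter level, and of Acan and Has3. It also limits those of Hbb-y (27.1 and 19.8 on Yap HET replicates 2 and 3), H2-Ab1 (80.1 and 70.0 on Yap HET replicates 1 and 3) and Rxrg (75.2 on Yap HET replicate 1).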

Other observations

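The gene groups in the first 2 paragraphs and all tests on explanations except those of the array splits and the neighbours of Yap1 were chosen after the data were seen. In Yap KO cells 4 of 6 Iroquois homeobox genes rose, namely Irx5 (log2 change 1.07 ± 0.07), Irx3 (0.63 ± 0.10), Irx1 (0.52 ± 0.11) and Irx2 (0.42 ± 0.10), while Irx4 had -0.07 ± 0.07 and Irx6 0.05 ± 0.11. Of 16 feedback targets of FGF and ERK signalling, 8 rose and 1 fell, with rises in the phosphatase gene Dusp4 (0.98 ± 0.11), the ETS factor genes Etv5 (0.74 ± 0.07), Etv4 (0.66 ± 0.06) and Etv1 (0.47 ± 0.05) and the inhibitor gene Spry4 (0.41 ± 0.05), and a fall in Egr1 (-0.27 ± 0.05). Of 10 genes of hyaluronan and cushion matrix, 8 rose and 0 fell, among them Has2 (1.29 ± 0.05), the link protein gene Hapln1 (0.77 ± 0.16) and the matrix genes Bgn (0.53 ± 0.12), Acan (0.33 ± 0.07) and Has3 (0.39 ± 0.10). The other risers, Postn, Tnc and Vcan, are also among the fibroblast and valve mesenchyme markers that rose, so this group is not independent of that list. Irx3 and Etv1 are among the trabecular markers that rose, so the Iroquois and feedback groups are not independent of the trabecular list. The Yap HET means of Acan and Has3 lay under the filter level of 85.7, so they cannot be told from background and the changes of these 2 genes are uncertain. With 1 array left out, the 4 Iroquois rises became 2 without any array except Yap HET replicate 2. The 8 feedback rises became 5 without Yap HET replicate 1, and the fall was lost without Yap HET replicate 1 or Yap KO replicate 1 or 2. The 8 matrix rises became 3 without Yap KO replicate 2, 4 without Yap HET replicate 1 and 5 without Yap HET replicate 3 or Yap KO replicate 3. With an estimated correlation the camera adjusted p was 0.074, 0.074 and 0.062 for these 3 groups. The camera p-values of the groups chosen after the data were seen were adjusted over those 6 groups alone, and so are not comparable with the values of the 37 fixed lists. The test also used the same arrays from which the groups were chosen. Its p-values therefore cannot serve as support for a shift of these groups, here or in the next paragraph.

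Of 22 Fanconi and recombination repair genes, 9 fell and 0 rose, including Tonsl (-0.57 ± 0.08), Bard1 (-0.52 ± 0.05), Dna2 (-0.45 ± 0.05), Fanca (-0.44 ± 0.08) and the checkpoint kinase gene Chek1 (-0.40 ± 0.05), with a median of -0.20 and adjusted p = 0.074 with an estimated correlation. Of 39 small nucleolar RNA genes, 8 fell and 1 rose, with a median of -0.25 and adjusted p = 0.23 with an estimated correlation. This shift lay mostly in 2 of the 3 Yap KO arrays, with medians relative to the Yap HET mean of -0.073 in replicate 1, -0.30 in replicate 2 and -0.34 in replicate 3. The 8 falls became 18 without Yap KO replicate 1 and 3 without Yap HET replicate 1 or 3 or Yap KO replicate 2 or 3, and the 1 rise became 2 without Yap KO replicate 1 and 0 without any other array except Yap HET replicate 3. Without Yap KO replicate 3 the median was -0.16. Of 27 semaphorin and plexin genes, 7 rose and 4 fell, among them Sema3c (0.76 ± 0.09) and Sema7a (0.67 ± 0.10) upward and Sema5a (-0.47 ± 0.06) downward, and the list did not pass the camera test (adjusted p = 0.37). The 7 semaphorin and plexin rises became 3 without Yap HET replicate 1 or Yap KO replicate 2 and 4 without Yap KO replicate 3. The 4 falls became 1 without Yap HET replicate 1 or Yap KO replicate 2 and 2 without Yap HET replicate 2 or 3 or Yap KO replicate 3.

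Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes past the threshold as the real one, namely the real one itself with 1353. The highest of the other splits was 0 with limma, and these 9 gave 118 to 1036 genes at an unadjusted p under 0.05 against 3851. With 10 splits the share cannot fall under 0.05. Each other split also has Yap KO and Yap HET arrays on both sides. A real difference between the groups would then widen the spread within a side and lower these counts. The counts of the other splits therefore do not show how many genes chance alone would give.

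Of 20 fibroblast and valve mesenchyme markers, 7 rose and 1 fell in cells sorted as cardiomyocytes by a green reporter, with a median of 0.32 (0.17 without Yap KO replicate 3) and adjusted p = 0.77 with an estimated correlation. A lower share of cardiomyocytes with all other types alike would raise epicardial, leukocyte and endothelial markers as well. The mesenchyme median exceeded that of 26 pooled epicardial and leukocyte markers by 0.5064 (permutation of genes as if independent, p = 0.00038, and 0.34 with p = 0.00369 without Yap KO replicate 3). It exceeded that of the 45 markers of all 3 types by 0.39 (permutation of genes, p = 0.00419). The compared lists were dimmer, with mean log2 intensities on Yap HET replicate 1 of 8.28 (epicardial), 7.59 (leukocyte) and 7.42 (endothelial) against 9.20. Changes of dim genes may be understated, so the size of these differences is uncertain. The pooled epicardial and leukocyte median was itself below 0, at -0.19. The difference from the 19 endothelial markers alone, of which 4 rose and 2 fell, was 0.23 and did not pass the test (permutation of genes, p = 0.145, but 0.0198 without Yap KO replicate 1 and 0.0393 without Yap KO replicate 2), so more mesenchymal and endothelial cells together stay open. More mesenchymal cells alone in the Yap KO sort stay open too: the collagen genes Col1a1, Col1a2 and Col3a1, abundant in such cells, had a mean log2 change of 0.2478 ± 0.135 (SE) over all arrays and 0.15 without Yap KO replicate 3, and the first value lies within 2 SE of 0.362, a bound set from the median of 0.72 of the markers that rose. Expression of these genes by cardiomyocytes that lack Yap was not tested and stays open as well, and 1 marker of the mesenchyme list, Tcf21, is also in the epicardial list.

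Of 21 hypoxia response genes, 12 rose and 0 fell, with a median of 0.35 (camera adjusted p = 2.81e-09), and adjusted p = 0.77 with an estimated correlation. Longer handling of the Yap KO hearts could raise immediate early genes as well, and their median was -0.179. Whether these genes would stay high through longer handling was not tested, nor whether the loss of Yap itself lowers them. Their direction therefore cannot settle this explanation, which stays open. Unequal shares of the sexes, within or between arrays, may add to differences, but with the level of Xist as a covariate the hypoxia median was 0.3386 (camera adjusted p = 1.17e-08 at the preset correlation, against adjusted p = 0.77 with an estimated correlation and no covariate). A higher share of trabecular cells would raise trabecular markers by at least as much, and their median lay -0.1991 from that of the hypoxia genes (permutation of genes, p = 0.0419), but -0.17 (p = 0.129) without Yap HET replicate 1 and -0.12 (p = 0.171) without Yap KO replicate 1, so this stays open. The loss of Yap itself, the difference that the design names, stays open too, as an untested explanation.

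Birc3 passed the threshold and Birc2 was higher without passing it, and both lie near Yap1 in the annotation. If a strain difference or the targeted allele affected the region, other nearby genes would be called more often, and 10% of the 20 nearest other tested genes were, against 9.91% of all other genes (two-sided Fisher's exact test, p = 1). The closest of these 20 genes on either side of Yap1 did not pass the threshold. They were Tmem123 (log2 change 0.15, limma adjusted p = 0.10) and Cfap300 (0.09, limma adjusted p = 0.57). An effect limited to Birc2 and Birc3 cannot be told apart from a response to the loss of Yap with these data, since so few genes lie beside it. In 1 further observation, Tnni3k, a cardiomyocyte kinase gene chosen after its values were seen, read 691, 1189 and 591 on the Yap HET arrays and 732, 252 and 264 on the Yap KO arrays, without passing the test (limma adjusted p = 0.13).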
